A study of Frankia casuarinae with 6 samples.

How the data were processed

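RNA was profiled from root nodules of Casuarina glauca that held Frankia casuarinae CcI3, a nitrogen-fixing actinobacterium that lives inside the nodule cells. The labels give 3 libraries from salt-stressed material and 3 from control material, grown at 28 degrees C for 21 days. Per the labels' protocols, RNA was extracted with lithium chloride and a silica column, and stable plant RNA and then stable bacterial RNA were depleted before Illumina library preparation. Nothing in the labels says that the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

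Per the series design text, the authors mapped the reads to the CcI3 genome with the CLC software. Its version, its settings and the use of strand are not given in the sources used here. Without known strand use, reads of overlapping and antisense genes cannot be told apart. The deposited table of each library lists 4499 genes with whole-number counts of total and unique gene reads. Per the file headers, the RPKM values of the authors (reads scaled by gene length and by the mapped total) stand beside the counts. A further deposited table holds the authors' own comparison of 4 of the 6 libraries, salt 1 and 3 against control 1 and 2, with a signed fold change and a test statistic (scores with no fixed range) from Baggerley's test. Its deposited p-values and FDR-adjusted p-values were read as the authors gave them. Its total gene reads equalled those of the library tables in 4499 rows of each of the 4 libraries. It holds 70 rows with no gene name, 14 fold changes that are not numbers and 20 columns of other values of the same libraries, none of which were used.

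The RPKM values imply a mapped total for each library that is larger than the sum over the listed genes. The share of that total on listed genes was 75.0% in salt 1, 78.0% in salt 3 and 66.4% in control 3, and it was 10.3% in salt 2, 15.2% in control 1 and 11.5% in control 2. Libraries above 50% are called high-yield and the others low-yield. This split was defined after the data were seen and it crosses the study's groups. What lies behind it is not given in the sources used here. The tables list no rRNA or tRNA rows, and what the rest of the mapped total holds was not analysed here. Reads that were not unique made up 0.708% to 1.23% of gene reads, so values of transposases and other repeated genes are uncertain.

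Product names came from the authors' table. Of the gene identifiers, 4019 were matched to the RefSeq table of assembly ASM1334v1 by locus tag and 182 by start and end, and 298 were not matched. Coordinates are those of the deposited tables on the CcI3 chromosome.

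Salt and control were compared with edgeR 4.0.16 in R 4.3.3: trimmed mean of M-values (TMM) normalization, the filterByExpr filter, a quasi-likelihood F test with group as the only term, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. The filter removed 316 genes. Levels are CPM, gene reads scaled to a common library total and by the TMM factors, as mean ± SD over the 3 libraries of a group. The standard error (SE) of an edgeR fold change was derived from the test, as the absolute log2 fold change divided by the square root of F. The 29 gene lists were fixed by regular expressions on names. Lists with at least 5 tested members, 25 of them, were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with an estimated correlation and with fry beside it. The 3 hydrogenase genes that a pattern had wrongly put in the nitrogenase list were removed after the data were seen. The rRNA and tRNA list matched 4 genes by name, all of them enzymes, and was left out. Values per library were compared with an exact permutation test, two-sided, for which the smallest possible p is 0.1.

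The genes named were chosen by a rule fixed before the data were examined, as were the design, the lists and most of the alternative settings. With fewer than 10 genes past the threshold, the rule takes the 8 genes with the smallest unadjusted p in each direction. It adds nifH, nifD, nifK, uptake hydrogenase, squalene-hopene cyclase, glutamine synthetases, trehalose synthesis genes, superoxide dismutases, catalases, GroEL, DnaK, potassium uptake genes and globins whatever their values, and up to 4 members of each list that passed.

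The alternatives were other size factors, DESeq2 1.42.0, limma-voom with quality weights, other low-count filters, unique reads, limma on log2(RPKM + 1), a replicate block, each library left out, and the authors' 4 libraries. Fits with library class as a covariate, within each class and with reads thinned to equal totals of gene reads were added after the data were seen. On simulated counts for the comparison of salt and control, with the real class means, library sizes and dispersions and 200 changed genes, the fit without a class term ran on 4129 genes and recovered 12% of the 2-fold and 65% of the 4-fold changes, with 0 false calls. The fit with the class term ran on 4167 genes and recovered 80% and 99%, with 11 false calls. The simulated counts came from a model with a class term and the same dispersion of a gene in both classes. The fit with the class term thus had the form of that model, and its recovery in the real libraries may be lower. Library pairs were checked for repeated deposits: the lowest chi-square per degree of freedom of any pair was 2.04 (salt 2 and control 2), so no pair was counted as 1 sample.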

Results

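The bacterial transcriptome of Casuarina glauca root nodules was sequenced with and without salt stress, with 3 libraries in each group. The comparison asks how Frankia casuarinae CcI3 inside the nodule changes its transcripts when the system is salt-stressed. Reads on the 4499 listed genes numbered 6208683 in salt 1, 224512 in salt 2 and 5682774 in salt 3. They numbered 261848 in control 1, 292215 in control 2 and 4426895 in control 3. The median gene had 463, 12 and 404 reads in salt 1 to 3, and 14, 15 and 306 reads in control 1 to 3. The mean number of gene reads did not differ beyond the spread between libraries (exact permutation p = 0.4, two-sided, n = 3 per group, smallest possible p 0.1).

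In both groups the most abundant transcripts were those of nitrogenase, the enzyme that reduces dinitrogen to ammonia. The structural genes nifD (Francci3_4487), nifK (Francci3_4486) and nifH (Francci3_4488), which lie next to each other at 5356614 to 5360605 on the minus strand, had the highest mean levels of all genes. Together they took 9.95% ± 1.06 of gene reads in control and 8.64% ± 1.69 in salt (SD, n = 3, exact permutation p = 0.3). After them came a GroEL chaperonin gene (groEL_4, 14150 ± 7428 CPM, SD, n = 6), an acyl transferase gene (Francci3_0991, 13435 ± 8682 CPM) and a cytochrome-c oxidase gene (Francci3_2009, 11878 ± 7129 CPM). These 3 levels pool libraries that differ: groEL_4 stood at 20699 ± 2978 CPM in salt 2, control 1 and control 2 and at 7601 ± 621 in the other libraries, Francci3_0991 at 21281 ± 1914 and 5589 ± 313, and Francci3_2009 at 18376 ± 222 and 5379.6 ± 585.1 (SD, n = 3). Their order changed too: they ranked 5, 4 and 6 among all genes in salt 2, control 1 and control 2, and 5, 9 and 11 in the other libraries.

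On the first principal component the libraries separated by yield and not by salt. The first principal component of log2 CPM held 52.3% of the variance and placed salt 1, salt 3 and control 3, the high-yield libraries, between -30.61 and -28.24, and the low-yield libraries salt 2, control 1 and control 2 between 19.48 and 44.08. Pearson correlations across genes were 0.987 to 0.991 between high-yield libraries, 0.883 to 0.904 between low-yield libraries and 0.851 to 0.900 between the classes. Genes are not independent replicates.

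**Figure D1:**
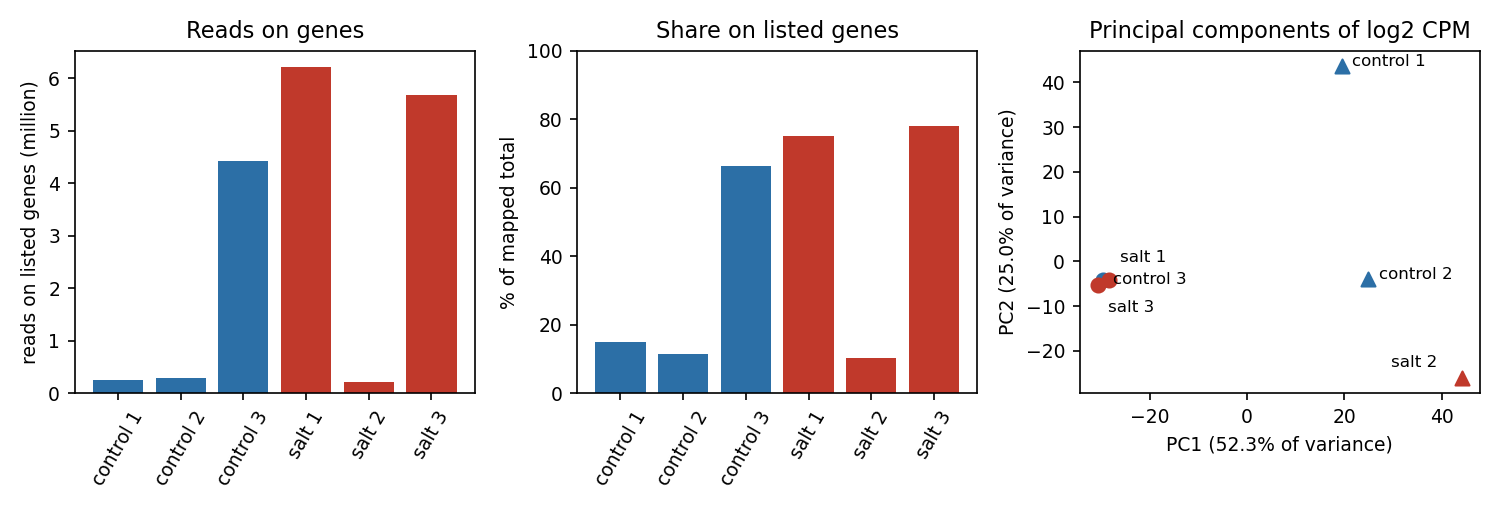
Reads on listed genes (left, axis as labelled), the percent of the mapped total on listed genes (middle) and principal components 1 and 2 of log2 CPM (right) for the 3 control (blue) and 3 salt (red) libraries; circles mark high-yield and triangles low-yield libraries. Control 3 lies with salt 1 and salt 3, and salt 2 lies on the side of control 1 and control 2.

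No single gene passed the test for a change with salt: edgeR called 0 of 4183 genes, with 41 at an unadjusted p under 0.05. DESeq2, limma-voom and limma on RPKM also called 0, with 16, 740 and 1 genes at an unadjusted p under 0.05. The 3 salt libraries lay all above or all below the 3 controls for 289 genes, 6.91% of those tested, where chance gives 10%. With library class as a covariate, a term added after the data were seen, edgeR called 2 of 4243 genes, with 283 at an unadjusted p under 0.05. With a library left out of that fit it called 6 genes without salt 2, 6 without salt 3, 3 without salt 1, 3 without control 2, 2 without control 1 and 1 without control 3.

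The gene that rose in that fit was Francci3_2774 (3270536 to 3271252, minus strand), a proteolytic subunit of the ATP-dependent Clp protease, which degrades damaged and regulatory proteins. It stood at 800 ± 64 CPM in salt and 405 ± 97 CPM in control (SD, n = 3), with every salt library above every control. Its log2 fold change was 1.02 ± 0.16 (SE, edgeR adjusted p = 0.0073) with the class term and 0.98 ± 0.22 without it (adjusted p = 0.999). The gene that fell was Francci3_1399 (1685095 to 1685832, plus strand), a hypothetical protein, at 44.5 ± 12.6 CPM in salt and 89.3 ± 9.8 CPM in control. Its log2 fold change was -1.20 ± 0.19 with the class term (edgeR adjusted p = 0.0073) and -1.12 ± 0.26 without it (adjusted p = 0.999). With control 3 left out of the fit with the class term, which leaves the salt term to the low-yield libraries with salt 2 as the lone salt library, Francci3_2774 had a log2 fold change of 0.94 (edgeR adjusted p = 0.195) and Francci3_1399 one of -0.57 (adjusted p = 0.728). Francci3_1399 also lost its call with salt 3 left out (adjusted p = 0.081) and with reads thinned to equal totals (-1.20, adjusted p = 0.211).

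The other genes with the smallest unadjusted p did not pass. Higher values in salt were seen for a type II secretion protein E (Francci3_1736, log2 fold change 1.09 ± 0.35), a cytochrome-c oxidase (Francci3_3821, 0.64 ± 0.22), a radical SAM protein (Francci3_1753, 0.64 ± 0.23), a luciferase-like protein (Francci3_2391, 0.85 ± 0.32) and the hypothetical proteins Francci3_2793 (0.79 ± 0.25), Francci3_1615 (0.75 ± 0.26) and Francci3_3463 (1.20 ± 0.43). Lower values were seen for transposases of the IS4 (Francci3_3313, -1.76 ± 0.54), IS110 (Francci3_1016, -1.20 ± 0.40) and IS66 (Francci3_0505, -1.02 ± 0.36) types. They were also seen for the ribosomal protein gene rpmB (-0.95 ± 0.34), a protein tyrosine phosphatase (Francci3_2325, -1.23 ± 0.45) and the hypothetical proteins Francci3_1400 (-0.79 ± 0.28) and Francci3_0969 (-0.73 ± 0.27). Each had an edgeR adjusted p of 0.999. Some of these values rest on very few reads in the low-yield libraries. Francci3_3463 stood at 4.35 CPM in control 1 (261848 gene reads), and Francci3_0505 and Francci3_2325 at 4.92 CPM in salt 2 (224512 gene reads). Francci3_1736, Francci3_2391, Francci3_3463, Francci3_0505 and Francci3_2325 did not pass the low-count filter within the low-yield libraries. With the class term Francci3_3313 stood at -1.02 ± 0.34. The transposase genes Francci3_3313 and Francci3_1016 did not pass the low-count filter with unique reads. Their values may therefore hold reads of other copies and cannot be assigned to these loci.

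Among the gene lists, 6 of 25 passed with camera's preset correlation, 5 lower and 1 higher in salt, and none passed with an estimated correlation or with fry. This count rests on a nitrogenase list from which 3 hydrogenase genes were removed after the data were seen. With the list as first written 4 lists passed, and the nitrogenase list (median -0.37, limma camera adjusted p = 0.0899) and the cell division list (adjusted p = 0.0547) did not. In each of the 6, 0 members passed singly and 0 passed when adjusted over the list alone. The corrected nitrogenase list (13 tested) had a median log2 fold change of -0.40, with 10 members negative (limma camera adjusted p = 0.026, adjusted p = 0.559 with an estimated correlation). The list still holds genes far from nifHDK that were matched by name, among them cimA (Francci3_3628) and the NifU-like gene Francci3_1943. In it nifD stood at 31313 ± 6314 CPM in salt and 41330 ± 7359 in control, nifK at 26665 ± 8590 and 35395 ± 7565, and nifH at 25584 ± 14105 and 30180 ± 9072 (SD, n = 3). The 3 low-yield libraries had 10.3% to 10.8% of gene reads on nifHDK and the 3 high-yield libraries 7.40% to 8.77%. With library class as a covariate the list's median was -0.04 (limma camera adjusted p = 0.582), and the log2 fold changes were 0.01 ± 0.12 for nifH, -0.25 ± 0.11 for nifD and -0.22 ± 0.11 for nifK (SE), against -0.24, -0.40 and -0.41 without it. The median was -0.79 with limma-voom and -0.94 in the 4 libraries of the authors' table. It ranged from -0.23 without salt 1 to -0.74 without salt 2 with a library left out, and the call was lost without salt 1 (adjusted p = 0.196), control 1 (-0.27, adjusted p = 0.293) and control 2 (-0.28, adjusted p = 0.128).

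Genes of energy metabolism were also lower as lists. ATP synthase and the respiratory chain (36 tested) had a median of -0.33 with 29 members negative (limma camera adjusted p = 0.00041, adjusted p = 0.559 with an estimated correlation). The member with the smallest unadjusted p, the cytochrome-c oxidase gene Francci3_3821, went the other way, at 75.5 ± 3.8 CPM in salt and 48.5 ± 3.2 in control. The cytochrome-c oxidase gene Francci3_2009 had a far higher level (mean 11878 CPM over the 6 libraries), so Francci3_3821 does not stand for all such transcripts. Cytochrome bd oxidase subunit I (Francci3_0256) was at 312 ± 49 CPM in salt and 441 ± 16 in control, and ATP synthase subunit B (Francci3_3711) at 1110.4 ± 100.6 and 1532 ± 201. The tricarboxylic acid cycle (20 tested) had a median of -0.25 with 16 negative (limma camera adjusted p = 0.010, adjusted p = 0.504 with an estimated correlation), with malate dehydrogenase (Francci3_3751) at 1076 ± 23 and 1450.3 ± 144.0 CPM and the succinyl-CoA synthetase alpha subunit (Francci3_0652) at 2033 ± 175 and 2752 ± 155. With the class term, the medians were -0.13 and -0.09 (limma camera adjusted p = 0.0996 for both), and 3 tricarboxylic acid cycle genes passed in edgeR when adjusted over the list alone. The respiratory chain median ranged from -0.20 without control 1, where the call was lost (limma camera adjusted p = 0.194), to -0.53 without control 3, and was -0.55 in the 4 libraries of the authors' table. The tricarboxylic acid cycle lost its call without salt 1 (-0.14, adjusted p = 0.122), control 1 (-0.22, adjusted p = 0.103) and control 2 (-0.16, adjusted p = 0.0595) and with RPKM (-0.21, adjusted p = 0.182), and its median was -0.38 in those 4 libraries.

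Ribosomal proteins (55 tested) passed as a list both without and with the class term, while their summed share of gene reads was 3.11% ± 0.33 in salt and 3.06% ± 0.41 in control (SD, n = 3, exact permutation p = 0.9). Their median was -0.15 with 45 members negative (limma camera adjusted p = 0.00055, adjusted p = 0.504 with an estimated correlation), and -0.20 with the class term (adjusted p = 0.0012, adjusted p = 0.764 with an estimated correlation). The call was lost without control 3 (median -0.19, limma camera adjusted p = 0.0641), with RPKM (-0.14, adjusted p = 0.158), in the 4 libraries of the authors' table (-0.21, adjusted p = 0.125) and with the class term and thinned reads (-0.13, adjusted p = 0.0619). Without control 1 the median was -0.10 (adjusted p = 0.044). The share was 3.29% to 3.47% in the high-yield and 2.65% to 3.06% in the low-yield libraries. When libraries were exchanged between the groups within each yield class, the list also passed with the class term in 3 of the other 8 arrangements, once with a smaller p (median 0.19, limma camera adjusted p = 3.9e-05). The medians were -0.17 within the 3 high-yield libraries, where control 3 is the lone control (limma camera adjusted p = 3.8e-05, adjusted p = 0.938 with an estimated correlation), and -0.20 within the 3 low-yield libraries (adjusted p = 0.353). Examples were rplA at 955 ± 62 CPM in salt and 1204 ± 115 in control, and rplS at 382 ± 29 and 516 ± 133. Conserved genes open to plastid, mitochondrial or other bacterial reads (17 tested) had a median of -0.29 (limma camera adjusted p = 0.026, adjusted p = 0.559 with an estimated correlation) and -0.15 with the class term (adjusted p = 0.133). Cell division, cell wall and WhiB regulators (42 tested) had a median of 0.15 with 32 positive (limma camera adjusted p = 0.046, adjusted p = 0.559 with an estimated correlation), with the sporulation and division gene ssgA (Francci3_1359) at 680 ± 54 CPM in salt and 517 ± 73 in control. Their median was 0.07 with the class term (adjusted p = 0.167), and the call was also lost with the nitrogenase list as first written, with RPKM (0.15, adjusted p = 0.182), in the 4 libraries of the authors' table (0.31, adjusted p = 0.0843) and without salt 3 (0.09, adjusted p = 0.058), control 1 (0.10, adjusted p = 0.286) or control 2 (0.13, adjusted p = 0.0595). The conserved genes lost theirs with RPKM (-0.23, adjusted p = 0.126) and without salt 1 (-0.21, adjusted p = 0.131), control 1 (-0.21, adjusted p = 0.293) or control 2 (-0.30, adjusted p = 0.0595). Leaving out control 1 left 1 list past the threshold and leaving out control 2 left 2.

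**Figure D2:**
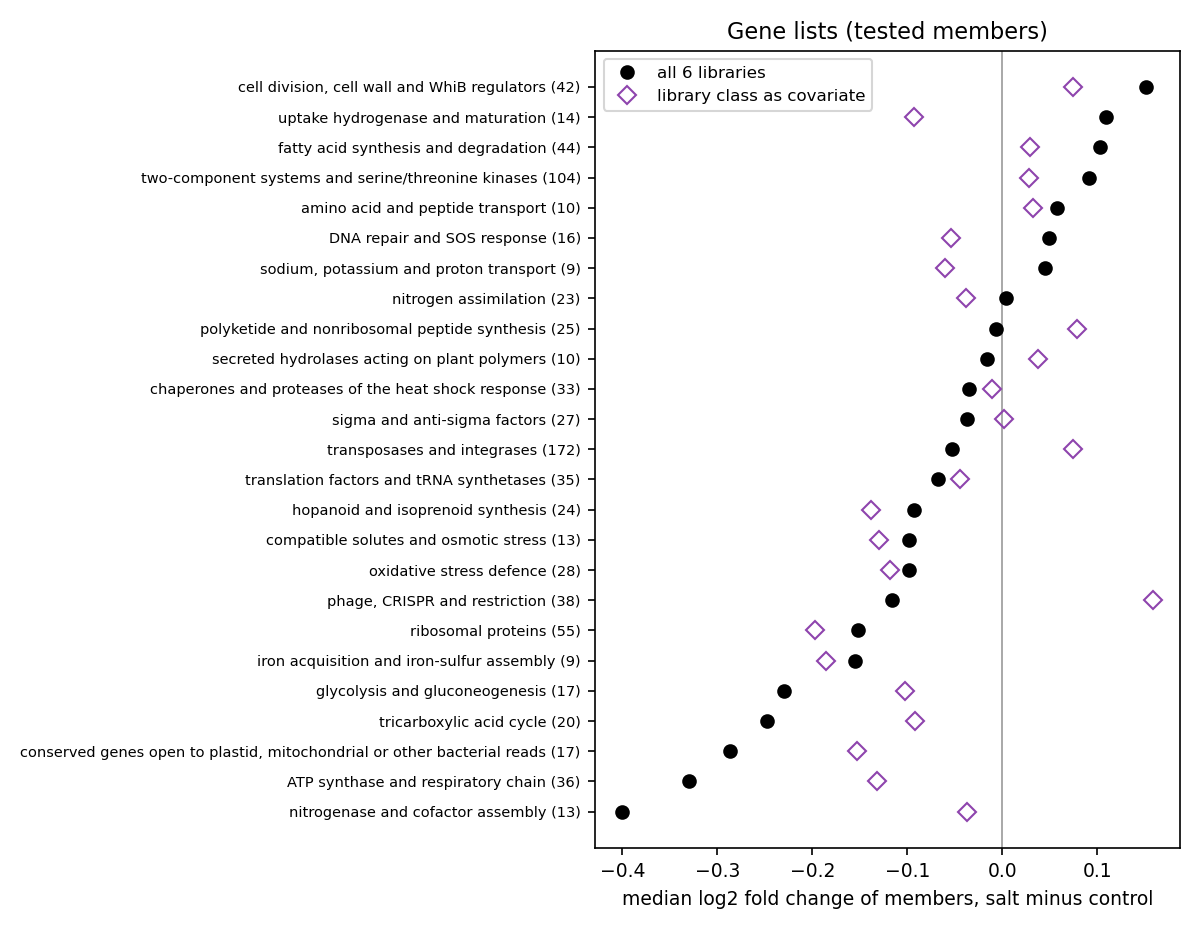
Median log2 fold change of the tested members (salt minus control, horizontal axis) for each of the 25 gene lists, in the fit of all 6 libraries (filled circles) and with library class as a covariate (open diamonds); the number of tested members is in parentheses. The nitrogenase median lay at -0.40 without and -0.04 with the covariate, and that of ribosomal proteins at -0.15 and -0.20.

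Gene groups tied to salt and stress did not pass in the fit of all 6 libraries. Compatible solutes and osmotic stress (13 tested, median -0.10), sodium, potassium and proton transport (9 tested, 0.05), chaperones and proteases of the heat shock response (33 tested, -0.03) and oxidative stress defence (28 tested, -0.10) had limma camera adjusted p of 0.353, 0.888, 0.560 and 0.076. Oxidative stress defence passed, lower in salt, without salt 1 (median -0.15, limma camera adjusted p = 0.034). The chaperone list had a positive mean and test direction with its negative median, and the transport list a negative mean and test direction with its positive median. Trehalose is a protective sugar, and its phosphate synthases Francci3_1478 and Francci3_4395 and the trehalose synthase Francci3_3679 had log2 fold changes of -0.04 ± 0.22, -0.14 ± 0.30 and 0.26 ± 0.24, with the first pair at 0.13 and 0.02 under limma-voom. The potassium pump subunit KdpA (Francci3_3287) was at 0.13 ± 0.26, and at -0.06 with the class term, and the TrkA-type genes Francci3_0415, Francci3_1322, Francci3_1323, Francci3_1892 and Francci3_2939 lay between -0.17 and 0.21, with a sign change of Francci3_1323 under DESeq2 size factors and RPKM. The superoxide dismutases Francci3_2817 and Francci3_2876 were at -0.41 ± 0.23 and 0.15 ± 0.37, and the catalases Francci3_1918 and Francci3_2949 at -0.49 ± 0.42 and 0.27 ± 0.18. The chaperonin genes groEL_1, groEL_2, groEL_3 and groEL_4 were at -0.22, 0.12, -0.03 and -0.73 ± 0.50, of which groEL_3 changed sign under RPKM, and dnaK_1 and dnaK_2 at 0.70 and -0.39. With the class term groEL_1 to groEL_4 stood at -0.40, 0.03, -0.05 and -0.27, and dnaK_1 and dnaK_2 at 0.68 and -0.14. In that fit the superoxide dismutases were at -0.25 and -0.00021 and the catalases at -0.12 and 0.23.

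Other symbiosis genes did not pass either. Uptake hydrogenase recycles the hydrogen that nitrogenase makes. Its large subunit (Francci3_4496) stood at 83.7 ± 13.7 CPM in salt and 123 ± 51 in control. The log2 fold change of this gene was -0.54 ± 0.33, and -0.16 ± 0.19 with the class term. The uptake hydrogenase list of 14 genes had a median of 0.11, a mean of -0.07 and a negative test direction (limma camera adjusted p = 0.672). Squalene cyclase (Francci3_0823), an enzyme of hopanoid lipid synthesis, stood at 1014 ± 158 and 1159 ± 115 CPM. Glutamine synthetases assimilate ammonia, and Francci3_0315, Francci3_3142, Francci3_3143, Francci3_3145 and Francci3_4059 had log2 fold changes of -0.08, 0.07, -0.31, -0.09 and 0.03, of which Francci3_3142 changed sign under limma-voom (-0.78), RPKM (-0.01), the replicate block (-0.05) and in the 4 libraries of the authors' table (-1.02, edgeR adjusted p = 4.4e-05), and lay between -0.70 and 0.38 with a library left out. With the class term Francci3_3142 stood at 0.41 ± 0.13 (edgeR adjusted p = 0.558), and it was at 0.20 within the high-yield and 0.66 within the low-yield libraries. Francci3_0315 was at 0.13 under limma-voom, and Francci3_3145 and Francci3_4059 at 0.09 and -0.01 with the class term. The globins Francci3_1149 and Francci3_2581 were at -0.30 ± 0.20 and -0.86 ± 0.79, and with the class term at -0.21 ± 0.16 and -0.16 ± 0.13. Too few for a test, the 4 cold shock and universal stress genes had a median of -0.26 and the 2 truncated haemoglobins one of -0.58 (-0.25 and -0.18 with the class term).

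The remaining lists had limma camera adjusted p above 0.05 in the fit of all 6 libraries. Their medians were -0.09 for hopanoid and isoprenoid synthesis, 0.00 for nitrogen assimilation, -0.07 for translation factors, -0.23 for glycolysis, -0.15 for iron acquisition, -0.04 for sigma factors and 0.09 for two-component systems. They were -0.05 for transposases, -0.01 for polyketide and nonribosomal peptide synthesis, 0.06 for amino acid transport, -0.02 for secreted hydrolases, 0.05 for DNA repair, 0.10 for fatty acid metabolism and -0.12 for phage, CRISPR and restriction. The last of these passed, lower in salt, with limma-voom (-0.35, limma camera adjusted p = 0.025), with RPKM (-0.18, adjusted p = 0.0014), in the 4 libraries of the authors' table (-0.46, adjusted p = 0.0089) and without salt 2 (-0.21, adjusted p = 0.035). With the class term its median turned to 0.16 (limma camera adjusted p = 0.171), and it was 0.03 within the high-yield and 0.25 within the low-yield libraries. Transposases passed with RPKM (-0.16, adjusted p = 0.00021) and without salt 2 (-0.12, adjusted p = 0.021), and hopanoid and isoprenoid synthesis without salt 3 (-0.19, adjusted p = 0.049), all lower in salt. With the class term the transposase median turned to 0.08 (limma camera adjusted p = 0.934), with 0.03 within the high-yield and 0.14 within the low-yield libraries. That of hopanoid and isoprenoid synthesis was -0.14 with the class term (limma camera adjusted p = 0.075).

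**Figure D3:**
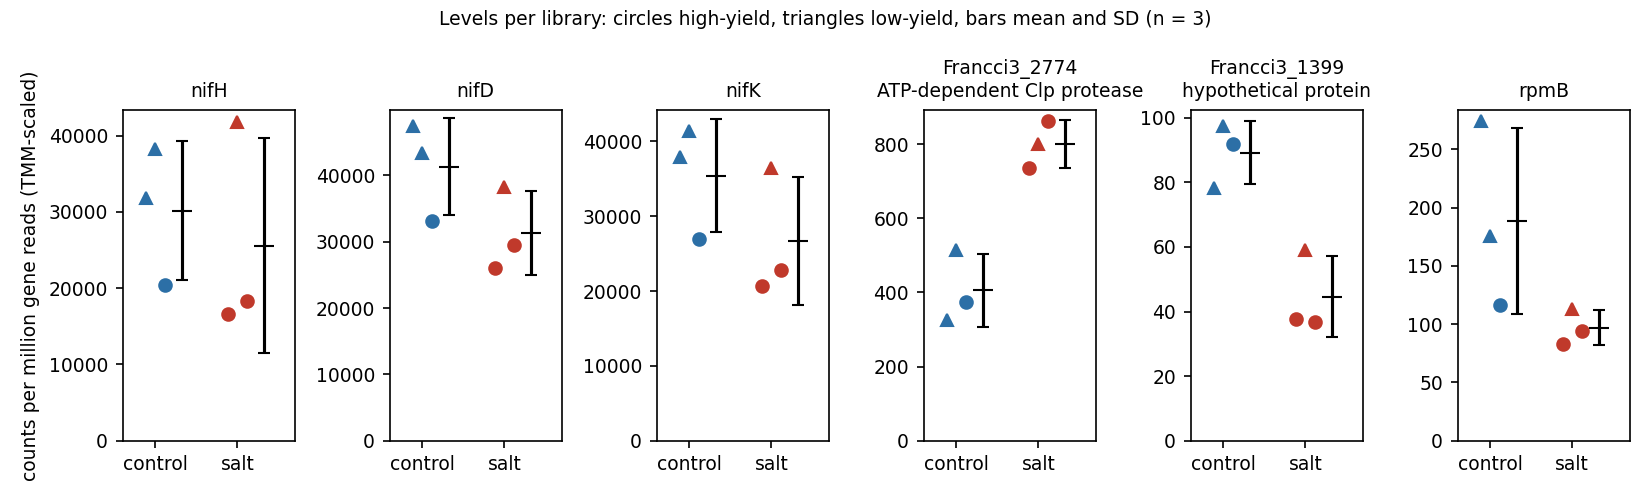
CPM per library (vertical axis, TMM-scaled) for nifH, nifD, nifK, Francci3_2774, Francci3_1399 and rpmB in control (blue) and salt (red); circles are high-yield and triangles low-yield libraries, and black bars give the mean and SD of the 3 libraries. For Francci3_2774 the salt libraries sit between 736 and 863 and the controls between 326 and 514.

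The authors' deposited table compared salt 1 and 3 with control 1 and 2, so every salt library in it was high-yield and every control low-yield. In the authors' deposited table, 0 genes had an FDR-adjusted p under 0.05 (smallest 0.174) and 64 had an unadjusted p under 0.05, 8 higher in salt, 53 lower and the rest without a numeric fold. Of the 61 of these with a numeric fold that were tested here, 53 had the same direction in the 6-library fit, which shares those libraries, and 22 with the class term. With edgeR, the same 4 libraries gave 926 of 4282 genes past the threshold, 354 higher and 572 lower. In the authors' deposited table, Francci3_2774 had a fold of 1.53 (p = 0.071) and Francci3_1399 one of -1.55 (p = 0.30). With edgeR within the 3 high-yield libraries 0 of 4405 genes passed, with 216 at an unadjusted p under 0.05. Within the 3 low-yield libraries 24 of 2905 passed, 21 higher and 3 lower in the lone salt library. The lone control of the first of these fits and the lone salt library of the second are assumed to vary like the other libraries of the fit. Some genes called in the second fit had the opposite sign within the high-yield libraries, such as Francci3_3218 (3.17 low-yield, -0.35 high-yield) and Francci3_0143 (1.68 and -1.06). Others kept their sign, such as Francci3_4114 (2.29 and 0.70). The genes called with the class term, Francci3_2774 and Francci3_1399, were not among them.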

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

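Fits with library class, within a class and with thinned reads were chosen after the data were seen, as was the correction of the nitrogenase list. The count of 0 genes held with DESeq2 size factors, upper-quartile factors, DESeq2, limma-voom, both other filters, unique reads, RPKM, an adjusted p under 0.1 and each library left out (lowest 0, highest 0). It was 926 in the 4 libraries of the authors' table (cause weighed under other observations), 2 with library class as covariate, 1 with the class term and thinned reads, and 24 within the low-yield libraries. Within a class the lone salt or control library is assumed to vary like the others. For these last settings the cause was not tested. Of the 6 lists, 4 passed with the nitrogenase list as first written, 4 in the 4 libraries of the authors' table, 2 with RPKM, 1 with the class term, 1 within the high-yield libraries, 0 within the low-yield libraries, 0 with the class term and thinned reads, 0 with an estimated correlation and 0 with fry. In the fit of all 6 libraries the estimated correlations were 0.35 for nitrogenase, 0.33 for the respiratory chain, 0.19 for conserved genes and 0.080 for cell division. They were 0.034 for the tricarboxylic acid cycle and 0.032 for ribosomal proteins, against the preset 0.01. The cause of the lost calls was not tested. Further lists passed with limma-voom (1), in the 4 libraries of the authors' table (1), with RPKM (2) and without salt 1 (1), salt 2 (2) or salt 3 (1). With a library left out 1 (control 1) to 8 (salt 2) lists passed, and 2 without control 2. The 6 lists kept their direction in every setting. The sample titles give numbers only. The column headers of the authors' table call the numbers of its 4 libraries batches and do not say whether both groups share a batch, so a pairing stays open. Deviations of same-numbered libraries from their group means correlated with r = -0.19, 0.40 and 0.62 across genes, and 4 of 6 libraries correlated best with their own number. Numbers 2 and 3 each join libraries of 1 yield class and number 1 joins both classes, so the correlations of deviations cannot tell pairing from class. Among the low-yield libraries salt 2 and control 2 correlated most (r = 0.904, other pairs 0.903 and 0.883). Among the high-yield libraries salt 3 and control 3 did (r = 0.991, other pairs 0.990 and 0.987). Class does not set this order within a class, but 1 pair in each class cannot show that the numbers are pairs. The replicate block gave 0 genes and 6 lists and changed no call of a named gene or of the 6 lists. Keeping rRNA and tRNA rows could not be run, since the tables used list none.

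Of 66 named genes, 48 kept the sign of their log2 fold change in every setting that tested them. Only 60 were tested without salt 1, without salt 3, within the low-yield libraries and with the class term and thinned reads. Without control 3 there were 61, and with unique reads 63. Apart from the 4 libraries of the authors' table, with 26 further named genes past the threshold, only the class term (2 genes, 1 with thinned reads) put a named gene past it. The other 18 changed sign in at least 1 setting, and the cause was not tested. None of them passed in the fit of all 6 libraries, and 1, Francci3_3142, passed after a sign change, in the authors' 4 libraries. RPKM moved the median of all genes by 0.91, and its values are relative to that shift, a choice made after 38 named genes had changed sign without it.

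With library class as covariate the log2 fold changes that changed sign were 0.012 for Francci3_4488, 0.085 for Francci3_3145, -0.0063 for Francci3_4059, -0.00021 for Francci3_2876, -0.060 for Francci3_3287 and -0.13 for Francci3_1323. With the class term and thinned reads they were 0.047 for Francci3_4488, 0.20 for Francci3_3145, -0.058 for groEL_2, 0.012 for groEL_3, -0.19 for Francci3_3287, -0.069 for Francci3_1322 and -0.033 for Francci3_1323. Within the low-yield libraries they were 0.26 for Francci3_4488, 0.031 for Francci3_3143, 0.040 for Francci3_3145, -0.73 for Francci3_2876, -0.13 for groEL_2 and -0.72 for Francci3_1323. Within the high-yield libraries they were 0.13 for Francci3_3145, -0.031 for Francci3_4059, -0.12 for Francci3_3287, 0.016 for Francci3_0415 and -0.0012 for Francci3_1322. With limma-voom they were 0.13 for Francci3_0315, -0.78 for Francci3_3142, 0.13 for Francci3_1478, 0.020 for Francci3_4395 and 3.8e-05 for groEL_1. In the 4 libraries of the authors' table they were 0.23 for Francci3_0315, -1.02 for Francci3_3142, 0.21 for Francci3_1478, 0.14 for Francci3_4395, -0.041 for Francci3_3679, 0.11 for groEL_1, 0.015 for groEL_3 and -0.020 for Francci3_2939. With the replicate block they were -0.054 for Francci3_3142 and -0.046 for Francci3_1323. With RPKM they were -0.013 for Francci3_3142, 0.012 for groEL_3 and -0.044 for Francci3_1323. With DESeq2 size factors there was -6.1e-05 for Francci3_1323. With each library left out, values ranged from -0.78 to 0.0074 for Francci3_4488, -0.22 to 0.12 for Francci3_0315, -0.70 to 0.38 for Francci3_3142, -0.26 to 0.12 for Francci3_3145, -0.056 to 0.14 for Francci3_4059, -0.12 to 0.10 for Francci3_1478, -0.12 to 0.42 for Francci3_2876, -0.27 to 0.25 for Francci3_1323 and -0.017 to 0.31 for Francci3_2939. Depth limits low genes in the low-yield libraries, where the median gene had 12 to 15 reads.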

Other observations

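The tests of explanations, the counts over splits and the fits with library class in this part were chosen after the results were seen. The fits behind the 926 genes, the 0 genes and the 6 lists were planned, the last with a list corrected afterwards. Of the 13 genes of the nitrogenase list, 9 were lower and 1 was higher in the high-yield than in the low-yield libraries, with salt as a covariate (edgeR; list median -0.68, limma camera adjusted p = 0.001, adjusted p = 0.499 with an estimated correlation). The list took 13.2% to 13.6% of gene reads in the low-yield and 9.29% to 10.8% in the high-yield libraries. In the nif cluster, nifW (Francci3_4480, 5351732 to 5352187, minus strand) stood at 1895 ± 205 CPM in the 3 low-yield libraries and 195 ± 31 in the 3 high-yield libraries (SD, n = 3), nifZ (Francci3_4479) at 967 ± 28 and 205 ± 21, and nifB (Francci3_4478), which makes the cofactor precursor, at 6998 ± 577 and 2186 ± 220. In the same cluster nifV (Francci3_4489) went the other way, at 3318 ± 473 and 5694 ± 541. The pyruvate:ferredoxin oxidoreductase gene nifJ (Francci3_2027, 2381844 to 2385431), a member of the list outside the cluster, stood at 8084 ± 1014 and 2738 ± 339. The structural gene nifD had a log2 difference of -0.45 ± 0.11 (SE, high minus low). NifN (Francci3_4484, -0.04 ± 0.13) did not pass. Nor did the NifU-like gene Francci3_1943 (-0.58 ± 0.57) and cimA (Francci3_3628, 0.33 ± 0.15), which also lie outside the cluster.

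Outside the nitrogenase list, the globin Francci3_2581 stood at 2004 ± 208 CPM in low-yield and 380.3 ± 21.1 in high-yield libraries, the acyl transferase gene Francci3_0991 at 21281 ± 1914 and 5589 ± 313, and the methionine sulfoxide reductase gene Francci3_2268 at 323 ± 113 and 19.5 ± 3.6. Higher in the high-yield libraries were mfd (Francci3_3926, transcription-coupled repair), at 1149 ± 21 against 584 ± 17 CPM, and the ribosome hibernation factor gene hpf (Francci3_0764), at 592 ± 60 against 249 ± 17. Besides the nitrogenase list, 2 lists passed, both lower in them: phage, CRISPR and restriction genes (39 tested, median -0.66, limma camera adjusted p = 0.001, adjusted p = 0.499 with an estimated correlation), and ATP synthase and the respiratory chain (36 tested, median -0.33, 14 members lower and 1 higher, limma camera adjusted p = 0.001, adjusted p = 0.544 with an estimated correlation). These classes are not groups of the study.

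Many genes differed between the high-yield and the low-yield libraries: edgeR called 1399 of 4243, 642 higher and 757 lower in the high-yield libraries. After all libraries were thinned to 224512 gene reads 1023 genes were still called, which argues against the total of gene reads alone. The trend with gene length held 0.615% of the variance of the called genes' log2 differences (Spearman rho 0.056 across these genes, which are not independent), which argues against gene length alone. What remains open is a difference in library preparation or in the nodule material behind each library, and reads of other organisms. Conserved genes open to such reads had a median of -0.26 high minus low (17 tested, limma camera adjusted p = 0.068). No biological explanation was tested, since the classes cross the groups.

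Many genes differed in the 4 libraries of the authors' table, 926 with edgeR. If salt were behind them, salt 2 minus control 3, the pair left out of that table, should go the same way. Signed by the call, its median was -1.10 on the log2 scale, with quartiles of -1.69 and -0.60, which argues against salt as the whole cause. If library class were behind them, control 3 minus salt 2 should go the same way, and 95.8% of the 926 genes did, which goes with library class. This reads the same pair of libraries in reverse and is not a separate test. After thinning to equal totals of gene reads 677 genes were still called, which argues against the total of gene reads alone. Of the 61 genes with an unadjusted p under 0.05 in the authors' deposited table, 0 had the direction of salt 2 minus control 3, again the same pair.

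A small salt effect shared between the classes was neither shown nor excluded. Across 2652 genes, the salt minus control log2 differences within the high-yield and within the low-yield libraries, which share no library, correlated with r = 0.14. The other 8 arrangements within classes gave -0.12 to 0.09. The real arrangement was the 1 of 9 with a correlation as high, and 9 arrangements are too few for a share under 0.05. With library class as a covariate, 2 genes were called and the highest of the other arrangements gave 1, so 1 of 9 arrangements gave as many. For gene lists it did not stand apart: 1 list, ribosomal proteins, was called, 4 of 9 arrangements gave as many, and the highest other gave 5. Ribosomal proteins were among the lists called in 3 of these other arrangements, which leaves the call of that list open. In the fit with group alone 0 genes were called, so that all 10 splits of the 6 libraries give as many by construction, and the highest other was the split by class with 1396, which points to a structure of the libraries. For gene lists, 6 were called, 1 of 10 splits gave as many, and the highest other was 5, also the split by class. With the nitrogenase list as first written the salt split gave 4 lists and the split by class 5. The splits are too few for a share under 0.05. A test of whether the salt effect differed between classes rests on 1 low-yield salt library and 1 high-yield control. It therefore cannot show that the effect is shared.

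Francci3_2774 (3270536 to 3271252) has a neighbour, Francci3_2773 (3269865 to 3270539), which was chosen after its values were seen. Francci3_2773 also encodes a Clp proteolytic subunit, and the 2 genes overlap by coordinates only at their ends. Its salt log2 fold change was 1.02 within the high-yield and -0.83 within the low-yield libraries, where Francci3_2774 had 1.10 and 0.93. Francci3_1400, which follows Francci3_1399, had -1.09 and -0.18, where Francci3_1399 had -1.30 and -0.57.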
